A study of Mus musculus with 4 samples.

How the data were processed

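RNA from primary keratinocytes of male mice was measured on 4 Affymetrix Clariom S Mouse arrays, 1 array for each combination of genotype and treatment. The genotypes were wild type (WT) and a line that the labels call an HMGB1 knockout (KO). The design text names the mutant mice K5-HMGB1, and how the allele was made is not given in the sources used here. Each culture was kept for 12 h in a keratinocyte medium, either untreated or with recombinant interleukin-4 (IL-4) at 100 ng/ml. Biotin-labelled cDNA was made from 100 ng of total RNA, per the labels' protocols. Technical replicates were not made, per the series' design text, and the labels give 1 sample per group, so no value has a replicate error.

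The authors deposited log2 expression values for 22206 transcript clusters and 6640 control rows. Per the submitters' processing notes, the values came from RMA in Affymetrix Expression Console 1.4. The design text names another program, the Affymetrix Exon Array Computational Tool, with no version. RMA corrects background, makes the arrays' distributions alike and summarises probes, so a global change in RNA content is removed and array medians lie close together, here between 5.10 and 5.15 for transcript clusters. The deposited log2 values reach 19.8, above the 16 that a 16-bit scanner count would give, and 233 to 245 clusters per array exceed 16. A further transformation may therefore have been applied, and its form is not given in the sources used here. A log2 difference is taken at face value below, while the hybridisation controls changed by only 0.66 to 0.71 log2 per log2 step of their nominal concentration, over levels up to 12.4.

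The authors also deposited a table for each of 2 comparisons, WT untreated against WT with IL-4 and WT with IL-4 against KO with IL-4. Each lists log2 values and a signed fold change, which is positive where the first named sample is higher, opposite to the sign used here. The columns matched the arrays to within 0.014 in the first table and 0.068 in the second. The first table held all 2610 clusters that differed at least 2-fold, and the second held 898 of 899. The array annotation is na36 on mm10, per the file headers. Gene symbols were used only where these tables pair them with a cluster. That gave symbols to 3178 clusters, of which 3059 had 1 symbol and 119 had several. Clusters with several symbols were counted and not named. Of the single symbols, 3001 matched a gene of the RefSeq annotation of GRCm38.p6, 2869 of them as a current symbol and the others through a synonym. Symbols are printed as the tables give them. The 19028 other clusters could be counted but not named.

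All comparisons are log2 differences between 2 arrays: IL-4 minus untreated within each genotype, and KO minus WT within each treatment. A cluster was counted where the difference was at least 2-fold and its highest value over the 4 arrays reached the median of all values of the table, 5.33, which kept 11456 clusters. "Rose" and "fell" are used for clusters that passed this threshold. With 1 array per group this is a size threshold and no p-value was computed for it. The only repeat available is the other pair of arrays: the IL-4 responses of WT and KO share no array, and neither do the KO minus WT differences of the untreated and the IL-4 cultures. Sharing no array does not make pairs independent, since the untreated and IL-4 dishes of a genotype may come from the same animals. A genotype difference seen under both treatments can then be a difference between animals. Agreement was described by Pearson's r and Spearman's rho across clusters, which are not independent replicates, and by the share of clusters with the same direction. The spread of the difference between the IL-4 responses of WT and KO (robust SD, from the median absolute deviation) was 0.53 log2. If chance variation is independent between the 4 arrays and alike in all clusters, its SD in a single difference of 2 arrays is at most 0.38. Variation shared by the dishes of a genotype or of a treatment cancels in this spread. The 0.38 is therefore no bound on shared variation, which stays in the KO minus WT or the IL-4 differences. Negative control rows varied more: of 5222 such rows, whose medians were 5.13 to 5.28, between 23.1% and 27.7% differed at least 2-fold in a comparison. Of all 22206 clusters, between 3.15% and 11.8% did. Between KO and WT untreated, 320 of 5442 filtered clusters with a mean level below 8.78 differed 2-fold, and 58 of 2053 with a mean of at least 12. The 95th percentile of the negative control values was 9.21, and 24.4% of cluster values lay above it.

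The 37 gene lists and the rule for naming genes were written before the data were examined. The list test had been planned over all members of a list. Because symbols exist only for clusters in the 2 tables, it was instead run on the members found in the table of that treatment or genotype contrast, and a list's median was placed among 10000 random lists of the same size from the same table, matched on mean level in 10 bins. Such members were already chosen for a difference of at least 2-fold in 1 pair of arrays, so a percentile says only whether they went up or down more than other listed genes did. In the other pair of arrays they were not chosen. A list gene that was not found there differed less than 2-fold, was not on the array, stood under another symbol or stood in a cluster with several symbols. Such clusters were not used in lists, also where they differed at least 2-fold. Lists with at least 5 members found in this way were evaluated. Limma fitted an additive model of genotype and treatment to the 4 arrays, with eBayes (trend) and Benjamini-Hochberg adjustment. It has 1 residual degree of freedom, which is the difference of the responses plus noise, and it is not a replicate check.

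The rule for naming genes, fixed with the lists, takes Hmgb1 and its family, the 10 largest rises and falls of each comparison with the same direction in the other pair, the 10 largest differences of the responses in each direction, list members at least 2-fold different in a comparison or else the 3 largest, and the 5 largest in each direction of each deposited table. Predicted genes were not named. Of the clusters past the threshold, 1537 of 2135 had a symbol for IL-4 in KO and 361 of 511 for KO minus WT untreated, so larger changes can lie among clusters without one.

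Results were recomputed under the alternatives that apply to each: no level filter, a stricter filter (mean at least 8.78, the 75th percentile), cyclic loess between arrays, centring on the 75th percentile, fold thresholds of 1.5 and 3, other treatment of clusters that share a symbol, and other choices of list members and random lists. Clusters were counted as deposited instead of averaged per gene, a change made after the data were seen. The scripts were tested on simulated data with a noise SD of 0.27 per array and 11257 clusters past the filter. For the IL-4 response in WT, 86% of clusters planted with a log2 change of 1.5 and 100% of those planted with 2 passed the 2-fold threshold, and so did 86 unchanged clusters. For KO minus WT with IL-4, the same changes stood in both arrays, so no difference was planted, and 89 clusters passed. Changes were planted only in clusters well above the level filter, and the simulated noise was alike in all clusters. The 89 is therefore not the number that chance would give in the real arrays. There, 25.1% of negative and 6.34% of positive control rows differed at least 2-fold between KO and WT with IL-4. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.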

Results

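Gene expression was measured in primary mouse keratinocytes, the epithelial cells of the epidermis, from WT and HMGB1 KO males, with and without 12 h of IL-4. HMGB1 is an abundant chromatin protein that also acts as an alarmin outside the cell. IL-4 is a cytokine of type 2 immune responses. Each of the 4 groups had 1 array of 22206 transcript clusters, so no difference below has a replicate check, and the number of arrays limits the precision. Across the 11456 clusters above the level filter, the deposited log2 values of WT and KO correlated at 0.986 in untreated cultures and at 0.984 with IL-4. Untreated and IL-4 arrays correlated at 0.927 to 0.947. The 95th percentile of the negative control rows was 9.21, and a log2 difference is uncertain in size where either value lies under it, or above 16, the limit of a 16-bit count. This holds for many of the large differences below. Where both values lie under 9.21 a difference is called dim, and passing 2-fold alone does not set it apart from variation of control rows. How many control rows passed larger sizes was not counted.

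The targeted gene was examined first. Hmgb1 (transcript cluster TC0500003648.mm.2; a protein-coding gene at chromosome 5, 149046702 to 149053057 in GRCm38) had a log2 value of 14.71 in untreated WT and 14.17 in WT with IL-4. In the KO arrays it was 7.97 untreated and 7.60 with IL-4. KO minus WT was -6.74 untreated and -6.57 with IL-4, and these 2 differences share no array. The KO values lie under 9.21, so the sizes are uncertain. The IL-4 arrays differed by 94.7-fold in the authors' deposited table. Hmgb1 had the largest fall among named genes in both KO minus WT comparisons. Which part of the transcript the probes cover, relative to the altered allele, is not given in the sources used here.

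**Figure D1:**
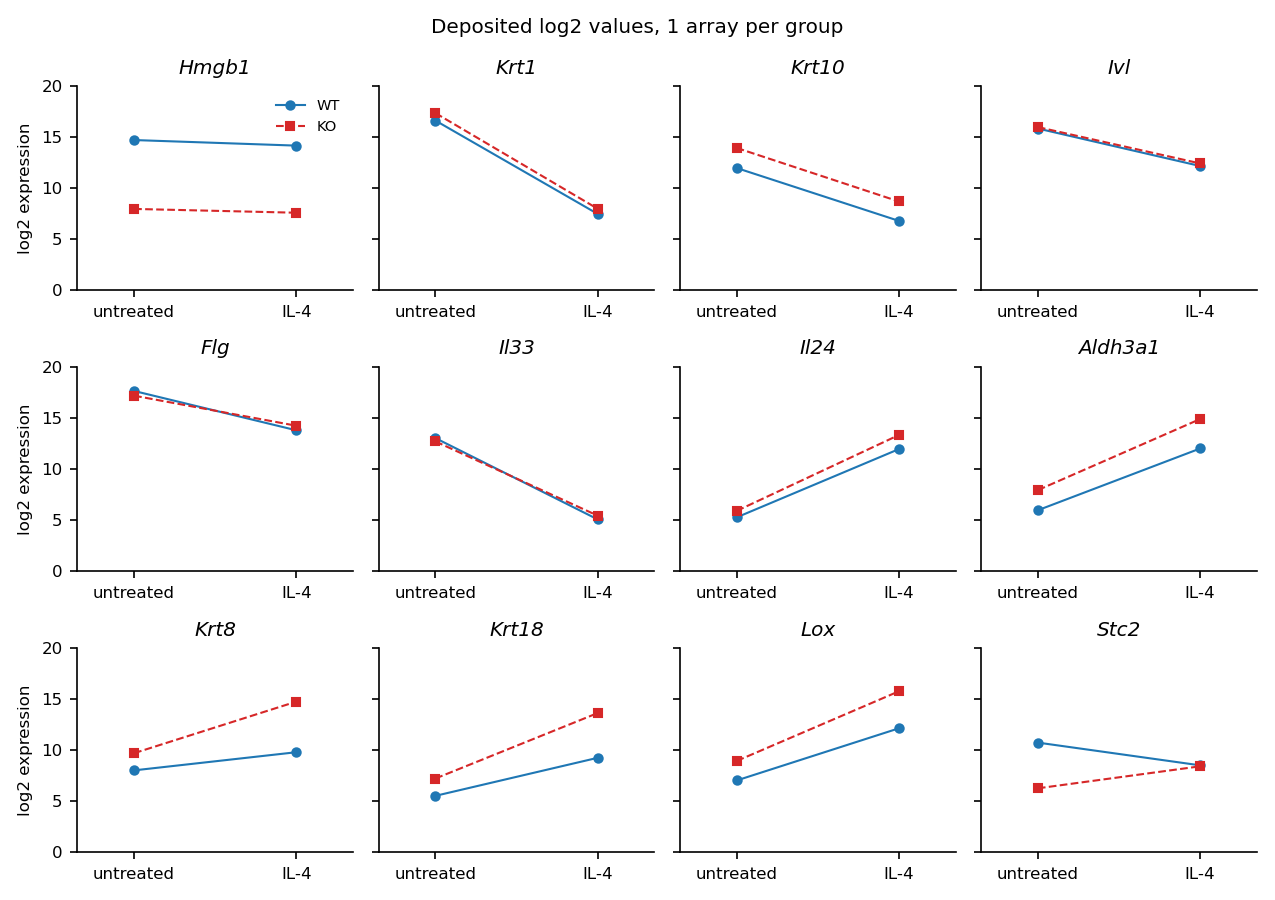
Deposited log2 expression (vertical axis) of 12 genes in untreated and IL-4 cultures (horizontal axis), with circles for WT and squares for KO, 1 array per point. Hmgb1 lies at 14.71 and 14.17 in WT and at 7.97 and 7.60 in KO, while Krt1 falls from 16.62 to 7.49 in WT and from 17.35 to 7.99 in KO.

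The comparison of IL-4 with untreated WT cultures asks how normal keratinocytes respond to the cytokine. The largest named fall was in a gene of terminal differentiation. Krt1, a keratin of the suprabasal layers, fell by 9.14 on the log2 scale, from 16.62 to 7.49. Of 60 genes on the cornified envelope list, 54 members were in the table of this comparison and all 54 were lower, with a median of -3.74. They included Krt10 (-5.17), the partner of Krt1, the envelope proteins Lor (-5.48) and Ivl (-3.67), the filaggrin family members Flg (-3.85), Flg2 (-6.30) and Hrnr (-6.90), the cross-linking enzyme Tgm1 (-4.56), and the desmosomal cadherin Dsg1a (-6.26). Krt1, Krt10, Lor and Flg2 were under 9.21 with IL-4, and Krt1, Flg, Hrnr and Dsg1a were above 16 untreated, so these sizes are uncertain. Of 22 listed genes of epidermal barrier lipid metabolism, 19 fell, among them Cyp4f39 (-6.23), Cers3 (-3.52) and Alox12b (-3.29), while 3 rose, among them Fads2 (1.91) and St14 (1.13). The list medians of both groups lay below those of all 10000 matched random lists.

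Several cytokine and host defence genes moved in opposite directions in the same WT cultures. Il33, an epithelial alarmin, fell by 7.96 and Il18 fell by 6.26, and the interleukin-1 family members Il1f8 (-3.97) and Il1rn (-3.37) fell too. Il24 rose by 6.68, the largest rise among named genes, followed by Tnfrsf26 (6.60), Calcb (6.22) and the aldehyde dehydrogenase Aldh3a1 (6.04). The untreated values of these 4 genes, and the IL-4 values of Il33 and Il18, lie under 9.21, so the sizes and their order are uncertain. Tnf (4.61), Il23a (4.36) and Lif (3.72) also rose, so the alarmin and interleukin list had 8 members up and 6 down. All 6 listed chemokines rose, led by the neutrophil attractant Cxcl1 (4.49) and the monocyte attractant Ccl2 (3.05). Clusters that carry a chemokine symbol beside other symbols were not used in the list, and they fell, between -1.53 and -1.68. Of 10 listed antimicrobial genes 9 fell, including S100a9 (-5.90), S100a8 (-4.37) and Defb4 (-3.95), and S100a7a rose by 3.24. Of 12 listed NF-kB targets, 11 rose, with Tnfaip3 at 3.05 and Icam1 at 2.78, and Bcl3 fell by 2.79. The differences of Il23a, Defb4 and S100a7a were dim.

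All 10 listed basal and hemidesmosome genes rose, such as the integrins Itga2 (2.52) and Itga3 (1.99) and the laminin chain Lamb3 (2.17). The junction list was divided, with 7 members up and 5 down and a median at percentile 55.1. Of 18 listed matrix, protease and TGF-beta genes 16 rose, including Mmp9 (5.27), Plau (4.56), Fn1 (4.02) and Tnc (3.21), and Tgfbi fell by 3.84. All 4 muscle markers in the table rose as well: Acta1 (3.50), Tagln (2.81), Cnn1 (1.29) and Acta2 (1.03). Of 15 listed NRF2 and oxidative stress genes 14 rose, including Nqo1 (3.21), Txnrd1 (2.80) and Gclm (2.21). The cross-linking enzyme Lox rose by 5.11. Of 34 genes on the IL-4 and STAT6 list only 4 were in the table, with Il24 and Cish (1.29) up and the receptor chain Il13ra1 (-3.15) and Serpinb3a (-3.13) down. The Y-linked genes Uty (1.52), Kdm5d (1.45) and Eif2s3y (1.21) rose as well, and the melanocyte markers Dct (-2.02) and Pmel (-2.18) fell. The differences of Acta1, Cnn1, Cish, Serpinb3a and the 3 Y-linked genes were dim.

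In all, 1250 clusters rose and 1076 fell in WT. Of 19 lists with at least 5 members, 9 had medians outside the central 95% of random lists: the cornified envelope, barrier lipid, antimicrobial and immediate early lists on the low side, and the basal, chemokine, NF-kB, NRF2 and matrix lists on the high side. By construction 5% of random lists lie outside. Their genes were drawn at random, while genes of a fixed list may vary together between dishes. The 5% is therefore not a chance rate for these lists, and the number outside was not tested against chance. The balance of rises and falls depended on scaling, since cyclic loess lowered the median response by 0.12 and gave 1033 rises and 1244 falls. The immediate early list came inside the central 95% without the level filter, at percentile 3.05, and with unmatched random lists, at 2.61, and the basal list, at 97.0, and the NF-kB list did so without their largest member.

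The same comparison in KO cultures asks which of these differences are also seen in the line labelled as an HMGB1 knockout. Krt1 fell by 9.36, Il33 by 7.27, Krtdap by 6.73 and Dsg1a by 6.61. All 54 cornified envelope members taken from the WT comparison were lower in KO too, 46 of them by at least 2-fold, with a median of -2.96. The barrier lipid median was -2.27, with 19 of 22 lower and 17 of them at least 2-fold. The largest rises included Il24 (7.43), Aldh3a1 (6.95), Lox (6.82), Tnfrsf26 (6.76) and the simple-epithelium keratins Krt18 (6.40) and Krt8 (5.05), where all but Krt8 were under 9.21 untreated. All 10 basal genes were higher, 7 of them at least 2-fold. Of the 15 NRF2 genes 14 were higher and 12 rose, with Nqo1 at 4.38 and Gsta2 at 3.97. All 6 chemokines were higher and 4 rose, with Cxcl1 at 3.87.

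In KO, 1045 clusters rose and 1090 fell. These list members had been chosen in the WT arrays and not in the KO arrays, and 8 of 19 lists had medians outside the central 95% of random lists. They were the cornified envelope, barrier lipid and antimicrobial lists on the low side and the basal, alarmin, NF-kB, NRF2 and matrix lists on the high side. The alarmin list was divided, with 8 members up and 6 down. The mitosis genes could be named only through the genotype comparison with IL-4. All 9 of them were lower with IL-4 in KO, 8 by at least 2-fold, as with Ccnb2 (-2.15) and Cdk1 (-1.86, dim), while in WT they lay between -0.30 and 0.53. These 9 genes were chosen for a low value in the KO IL-4 array, which enters this difference.

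**Figure D2:**
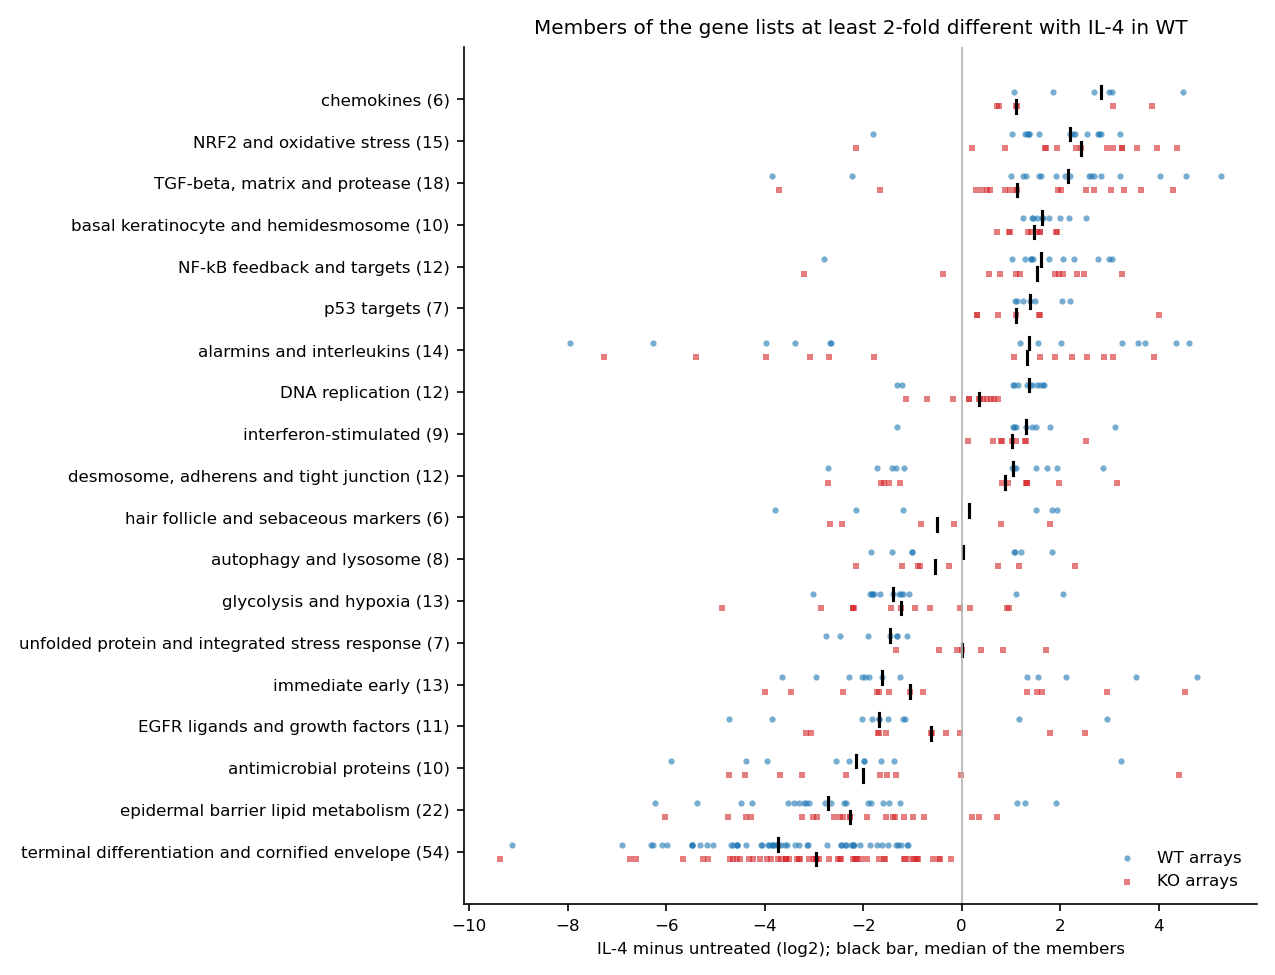
Log2 difference, IL-4 minus untreated (horizontal axis), of members of 19 gene lists that differed at least 2-fold in WT (vertical axis, number of clusters in parentheses), with blue circles for the WT arrays, red squares for the KO arrays and black bars for medians. The cornified envelope medians are -3.74 in WT and -2.96 in KO, and the integrated stress list is at -1.46 in WT and 0.01 in KO.

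The 2 responses to IL-4 were compared cluster by cluster. Of the 2326 clusters past the threshold in WT, 93.8% had the same direction in KO, against 72.9% of all 11456 clusters. Among the 2326, 1380 also passed the threshold in KO in that direction. Of these 661 rose and 719 fell in both, where independent lists of these sizes would share 114 and 102. Across all 11456 clusters Pearson's r was 0.81 and Spearman's rho 0.66. The clusters with a mean level of at least 12 had the highest r, 0.87, and those with a mean level below 8.78 had 0.74. Both genotypes had Krt1, Il33, Dsg1a, Them5 and Cyp4f39 among the 10 largest named falls and Il24, Tnfrsf26, Aldh3a1, Lox, Slc4a11 and Atp1b1 among the 10 largest named rises. Part of this sharing follows from the naming rule, which asks for the same direction in the other pair and needs a symbol from the deposited tables.

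**Figure D3:**
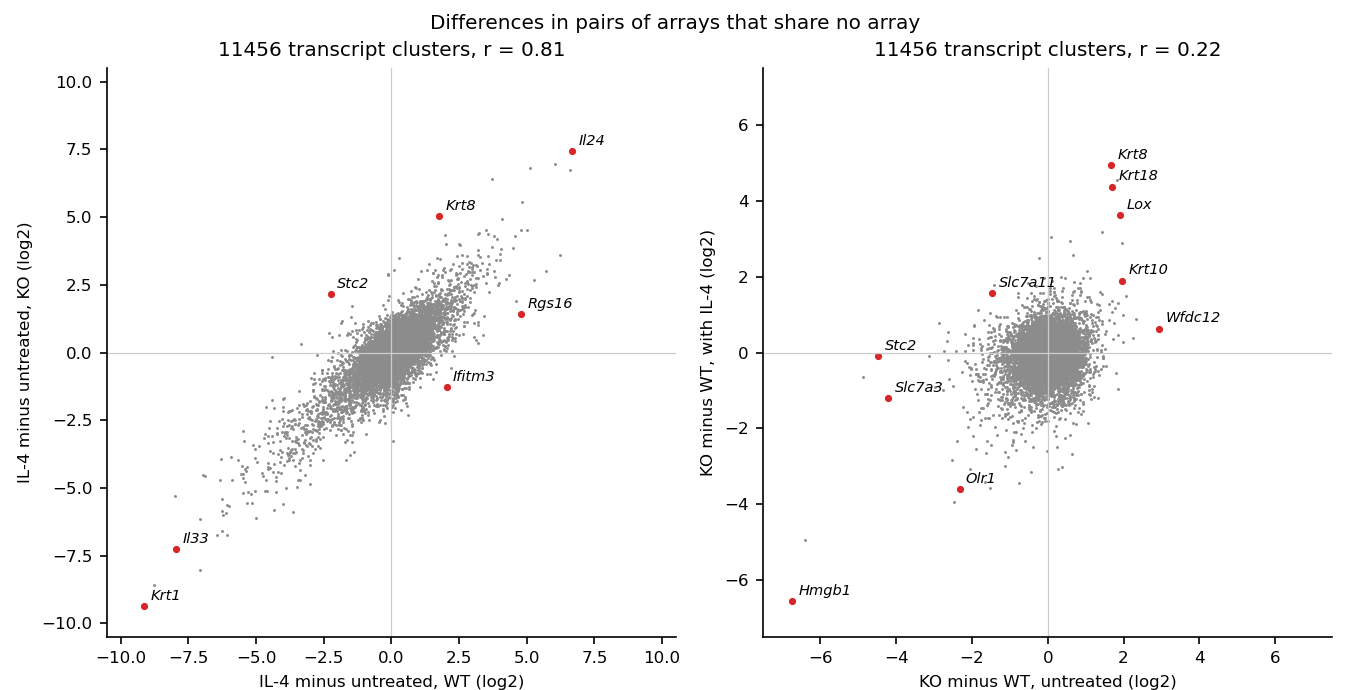
Log2 differences of 11456 transcript clusters (grey points) with named genes in red, in pairs of arrays that share no array. Left, IL-4 minus untreated in WT (horizontal) and KO (vertical), r = 0.81; right, KO minus WT in untreated (horizontal) and IL-4 cultures (vertical), r = 0.22, where Hmgb1 lies at -6.74 and -6.57.

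The untreated cultures show the difference between KO and WT without the cytokine. Stc2, a secreted glycoprotein gene, was lower by -4.47, the cationic amino acid transporter Slc7a3 by -4.20, the transcription factor Atf5 by -3.13, the peptide hormone gene Adm2 by -2.97 and the pseudokinase Trib3 by -2.64. All 7 named members of the unfolded protein and integrated stress list were lower in KO, 6 of them at least 2-fold, including Chac1 (-2.18), Cth (-1.81), Asns (-1.74), Psat1 (-1.70) and Atf4 (-1.17). With IL-4 the same 7 genes lay between -0.57 and 0.68. They were named because they fell with IL-4 in WT, and that difference shares the WT untreated array with this one. Over all 1076 clusters that fell in WT, the median KO minus WT difference untreated was -0.45, against -1.74 for the 7. The difference of Adm2 was dim, and Stc2, Slc7a3, Atf5, Trib3, Chac1 and Cth were under 9.21 in KO.

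Genes higher in untreated KO included Wfdc12 (2.94), Apoe (2.33), the amino acid transporters Slc43a2 (2.24) and Slc7a8 (2.06), the smooth muscle genes Acta2 (1.99) and Tagln (1.98), Krt10 (1.97) and Lox (1.91). Slc7a8 (1.49), Krt10 (1.90), Lox (3.62), Aldh3a1 (1.97 untreated and 2.88 with IL-4) and Tns3 (1.86 and 1.32) were at least 2-fold higher with IL-4 as well. Among genes at least 2-fold lower in both treatments were Htr1b (-2.54 and -2.84), Lrrn4cl (-2.39 and -2.32), Klk5 (-2.06 and -1.74), a serine protease of the stratum corneum, and the prostaglandin synthase Ptgs2 (-1.57 and -1.72). Dim differences were those of Wfdc12, Slc43a2, Lox, Aldh3a1 and Tns3 untreated, Krt10 and Klk5 with IL-4, and Htr1b and Lrrn4cl in both. Of 55 named cornified envelope genes, 47 were lower in untreated KO, 10 by at least 2-fold, with a median of -0.53. Most of these were also chosen through the WT untreated array. Over all 1076 clusters that fell with IL-4 in WT, the median KO minus WT difference untreated was -0.45, not far from -0.53.

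Untreated, 154 clusters were higher and 357 lower in KO by at least 2-fold. With IL-4, 71.4% of these 511 had the same direction, against 53.6% of all 11456 clusters, and 107 passed the threshold in that direction. Across 11456 clusters the 2 genotype differences had a Pearson's r of 0.22 and a Spearman's rho of 0.12. The 28 clusters higher in both and the 79 lower in both compare with 2.49 and 13.8 for independent lists. Only 4 lists could be evaluated with members from the genotype table, and the mitosis list, at a median of 0.52, lay outside the central 95% of random lists on the high side.

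With IL-4, large rises in KO relative to WT included keratins of simple epithelia. Krt8 was higher by 4.95 and Krt18 by 4.38, against 1.68 and 1.70 untreated. Krt7, another keratin of simple epithelia, went the other way, at -2.09 with IL-4 and -0.83 untreated. The untreated difference of Krt18 was dim. Angptl7 was higher by 4.56, Lox by 3.62 and Ankrd1 by 2.95, with Angptl7 and Ankrd1 under 9.21 in WT. The mesenchymal genes Vim (1.98) and Sparc (1.71), both on the fibroblast list, were higher too, and Vim was 1.13 higher untreated. These were the only 2 of 21 fibroblast markers in the table. The melanocyte markers Tyrp1 (1.62) and Dct (1.56) were also higher.

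Several antioxidant and detoxification genes were higher in KO with IL-4. All 10 NRF2 list members in the table were at least 2-fold higher, with a median of 1.54, and included Gsta4 (1.96), Gclm (1.71), Srxn1 (1.69), Gsta2 (1.60), the cystine transporter Slc7a11 (1.57) and Nqo1 (1.32). Aldh3a1 (2.88) and Adh7 (2.58) were also higher. The same 10 members had a median of 0.16 in untreated cultures, where 7 were higher. Over all 20 named members, of 35 genes on the list, 16 were higher with IL-4, with a median of 1.01. That median includes the 10 members chosen for a 2-fold difference in this same comparison. The other 10 had a median of 0.39, with 6 of them higher.

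Some cytokine, protease and cell division genes were lower in KO with IL-4, and others were not. Tnf was lower by -2.24, and the chemokines Cxcl3 (-1.42), Ccl2 (-1.26) and Ccl20 (-1.10) were lower, while Il24 (1.38) and Lif were at least 2-fold higher. The matrix metalloproteinases Mmp13 (-2.63) and Mmp9 (-2.61) and the activin subunit Inhba (-2.75) were lower, and 5 of 6 listed matrix and TGF-beta genes went this way. Further genes lower in KO were Olr1 (-3.59), the complement protease C1s1 (-3.57), the VEGF receptor Flt1 (-3.43) and Stmn2 (-3.43). Their KO values lie under 9.21, so these sizes are uncertain, and the difference of Stmn2 was dim, as were those of Cxcl3 and Ccl20. The monocarboxylate transporter Slc16a3 was lower by -3.08, against 0.27 untreated. All 9 listed mitosis genes were lower, from -1.02 for Top2a to -1.39 for Racgap1, while 8 of the 9 were higher in untreated KO, Cdk1 by 1.21 (dim). The list holds 35 genes, and the median of these 9, -1.11, lay at percentile 71.3 of random lists from a table in which 422 of 602 named clusters were lower.

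**Figure D4:**
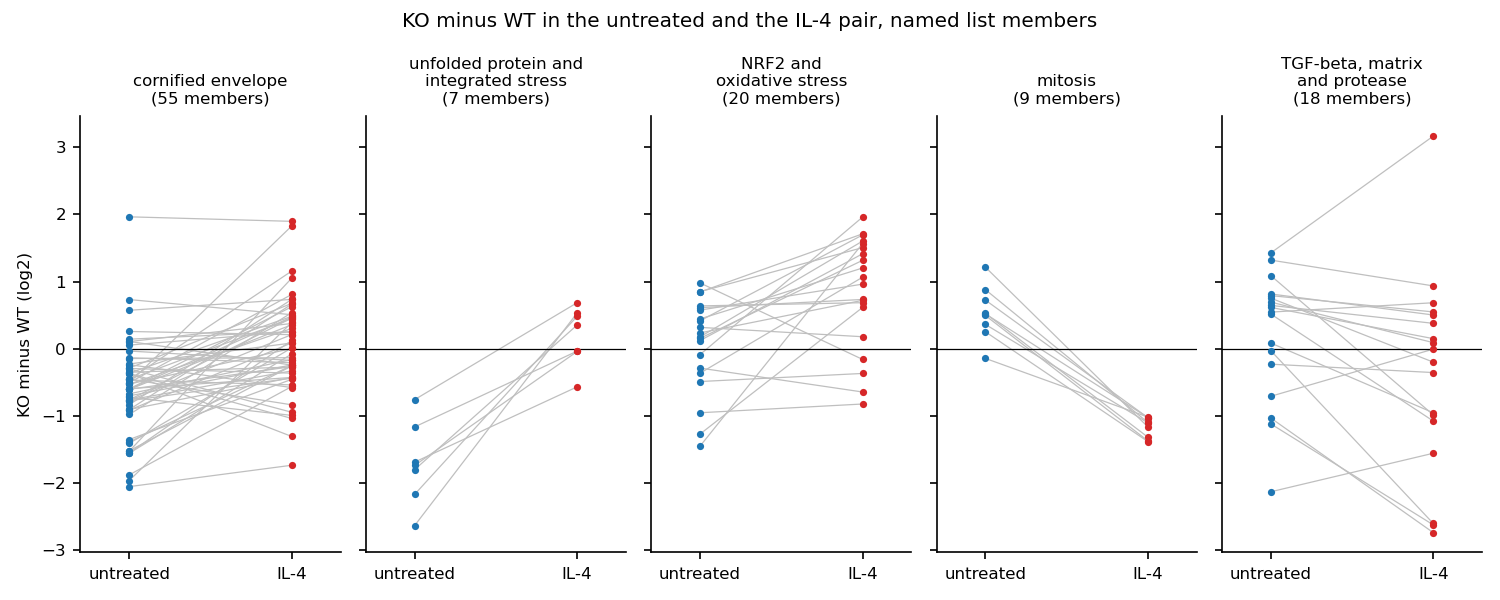
KO minus WT log2 difference (vertical axis) of the named members of 5 gene lists in untreated (blue) and IL-4 cultures (red), with a line joining the values of each gene. All 7 integrated stress genes are below 0 untreated, 16 of 20 NRF2 genes are above 0 with IL-4, and all 9 mitosis genes are below 0 with IL-4.

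With IL-4, 185 clusters were higher and 442 lower in KO by at least 2-fold. Of these 62.7% had the same direction untreated, against 53.6% of all 11456 clusters above the filter. The share was 68.6% of those higher and 60.2% of those lower. Among those of the chosen clusters with a mean level of at least 12 it was 47.4% of 78. The NRF2 list was outside the central 95% of random lists on the high side and the matrix list on the low side, and the cornified envelope list, with 4 of 7 members higher, and the mitosis list were not. With members from both deposited tables, a setting chosen after seeing the data, the matrix list had a median of -0.11. The mitosis list, at -1.11, then fell outside on the low side. Its 9 members had all been chosen for a 2-fold difference in this comparison, as had only 602 of the 2568 named clusters then drawn from. That placement therefore follows from the choice of members.

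The IL-4 responses of the genotypes were then subtracted, KO minus WT. The difference was at least 2-fold in favour of KO for 506 clusters and of WT for 666. The response was higher in KO by 4.38 for Stc2, 3.27 for Krt8, 3.21 for Ttc9 and 3.02 for Slc7a11. It was lower in KO by -3.38 for Rgs16, -3.35 for Slc16a3, -3.32 for Ifitm3 and -2.71 for Tnf. Of these, Stc2, Krt8, Ttc9, Rgs16 and Tnf had at least 1 of their 4 values under 9.21. For genes chosen by the mean response of both genotypes, the median difference was -0.12 over 973 rising and 0.14 over 968 falling clusters. In WT these had median responses of 1.52 and -1.82. The direction of the median differences turned with the choice of genes: choosing by the WT response gave -0.43 and 0.42, and choosing by the KO response gave 0.26 and -0.23.

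In the additive limma model with Benjamini-Hochberg adjustment at 0.05, 1213 clusters were higher and 1109 lower with IL-4. For genotype, 0 clusters were higher and 2 were lower in KO, with 903 at an unadjusted p under 0.05. Limma without the intensity trend gave 0 and 2 as well, with 927. The lower pair were Hmgb1, with a log2 difference of -6.65 and an adjusted p of 0.00021, and a cluster that carries 2 predicted pseudogene symbols, with -5.68 and an adjusted p of 0.00996. Both were lower in KO under each treatment. With 1 residual degree of freedom this fit treats any real difference between the IL-4 responses as noise. The balance of its IL-4 term depended on scaling, since after cyclic loess more clusters were lower than higher.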

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

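The difference of responses was not tested for any gene here, since each group has 1 array. Of the tests given for the patterns, the one on dim clusters was set before its result was seen and the others after.

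Some named genes moved at least 2-fold with IL-4 in opposite directions in the 2 genotypes. KO minus WT differences of the response were 4.38 for Stc2 (-2.22 in WT and 2.15 in KO), 3.17 for Trib3 (-1.46 and 1.72), 2.99 for Slc7a3 (-1.82 and 1.17), 2.95 for Pck2 (-1.85 and 1.10) and 2.45 for Aldh18a1 (-1.36 and 1.09). The opposite order was seen for Ifitm3 at -3.32 (2.04 and -1.29) and Hmgn5 at -2.32 (1.04 and -1.28). Both values lay under the 95th percentile of the negative control rows, 9.21, for Hmgn5 in each genotype and for Stc2, Slc7a3 and Pck2 in KO, where chance variation was not excluded. Above the level filter, 7 clusters rose in KO and fell in WT, and 2 did the reverse.

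Other named genes had KO minus WT differences of at least 2-fold in opposite directions with and without IL-4. The change between treatments was 3.21 for Ttc9 (-1.43 untreated and 1.78 with IL-4), 3.02 for Slc7a11 (-1.46 and 1.57), 2.96 for Rassf6 (-1.85 and 1.12) and 2.58 for Lor (-1.53 and 1.05). It was -2.92 for Tmprss11b (1.07 and -1.85), -2.38 for Cdk1 (1.21 and -1.17) and -2.36 for the polymerase gene Pold1 (1.13 and -1.23). Cdk1, Pold1 and Rassf6 were under 9.21 on every array, as were Ttc9 untreated and Lor with IL-4 in both genotypes, so chance variation was not excluded for them. In all, 11 clusters did this, against 107 that passed the threshold in the same direction under both treatments.

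All 54 cornified envelope members were lower with IL-4 in both genotypes, 46 of them by at least 2-fold in KO. Random variation of single dishes is argued against by dishes given the same treatment, whose list medians differed by at most 0.57 in size, against falls of -3.74 in WT and -2.96 in KO over the same 54 members. A level-dependent shift between arrays is argued against by cyclic loess, after which the KO median was -3.04. A response of keratinocytes to IL-4 may account for the pattern, as a hypothesis. Any handling difference shared by both treated dishes follows the same split of the arrays as IL-4 and was not tested.

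The higher NRF2 genes in KO with IL-4 rest on 1 array of each genotype. A level-dependent shift is argued against, since cyclic loess estimated a shift of at most 0.036 for any of the 10 members, whose median was 1.54. A genotype difference that does not need IL-4 could not be told apart from one that does. The 10 members not chosen for a genotype difference had medians of 0.27 untreated and 0.39 with IL-4, and 6 of 10 were higher in each. They were named only through the WT response, so each differed less than 2-fold between KO and WT with IL-4. That choice holds down their median with IL-4, so it cannot decide the question. Their SD untreated, 0.75, is that of single members and not of a median. The 10 chosen members had 0.16 untreated, but all 185 clusters chosen as higher with IL-4 dropped in a similar way, from a median of 1.25 to 0.28. Variation of the KO dish with IL-4 and an effect of HMGB1 loss on the response to IL-4 both stay open and untested.

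The genotype differences with and without IL-4 had an r of only 0.22 across clusters. Noise of dim clusters is argued against as the whole cause, since r was 0.23 among the 6014 clusters in the upper range of levels. Level-dependent shifts held at most 0.20% of the variance of these differences, as estimated by cyclic loess. Genotype effects that depend on IL-4 and differences between single dishes would both give this pattern, and neither was tested.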

How the results depend on the processing

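The settings for the negative control filter, the averaging of symbols, both deposited tables and the other random seed were chosen after seeing the data. With 1 array per group no replicate could be left out, and no paired analysis was possible across replicates because each group has 1 array. The additive model compares treatments within genotype and leaves 1 residual degree of freedom. All 46 list directions and sides of the threshold were the same with cyclic loess and with another random seed. All 793 differences of named genes kept their direction under cyclic loess and under centring and moved by at most 0.13, but 29 of them came under 2-fold with cyclic loess and 27 with centring. Loess changed the median response to IL-4 by -0.12 in WT and -0.10 in KO. Under the other settings 43 (no level filter), 45 (random lists not matched), 43 (without the largest member) and 38 (both tables) of the 46 were the same. For IL-4 in WT, the alarmin list went outside the central 95% without its largest member and with both tables (percentile 98.5), the growth factor list without the level filter (2.15) and with both tables (2.49), and the DNA replication list with both tables (97.8). For IL-4 in KO, the chemokine list did so without the level filter (98.5) and the glycolysis list with both tables (2.17). For KO minus WT untreated, the cornified envelope list did so with both tables (percentile 0). The Hmgb1 differences stayed between -6.50 and -6.73 under these scalings. Signal over background limits dim genes: the strict filters kept fewer clusters by construction. With the mean of the arrays at least at the 75th percentile, rises and falls numbered 680 and 580 for IL-4 in WT, 557 and 617 for IL-4 in KO, 48 and 143 for KO minus WT untreated, and 63 and 193 with IL-4. With the highest array above the 95th percentile of the negative control rows they were 775 and 690, 653 and 721, 56 and 194, and 84 and 237, in the same order. At a fold of 1.5 they were 2546 and 1953, 2345 and 2002, 866 and 1069, and 865 and 1372. At a fold of 3 they were 462 and 606, 388 and 572, 23 and 92, and 37 and 96. Without a level filter 254 clusters were higher in untreated KO and 381 in KO with IL-4. Requiring the same direction untreated left 266 lower in KO with IL-4. Correlations among fixed-list genes only were 0.92 for the IL-4 responses and 0.36 for the genotype differences. The difference of the responses was -0.43 for rising and 0.42 for falling clusters chosen in WT, and reversed to 0.26 and -0.23 when chosen in KO. Choosing genes in 1 genotype favours large values of that genotype, so these follow from the construction. With members from both tables, the lists outside the central 95% for KO minus WT untreated went from 1 of 4 to 7 of 21, and the matrix and TGF-beta list there reversed to 0.58. That setting adds members chosen through the WT untreated array. For IL-4 in KO it adds Aldoc and Slc16a3 to the glycolysis list, which were chosen through the KO IL-4 array that enters that difference. The cause of the other changes was not tested.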

Other observations

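The tests of this part are those already given, and the values below were picked out after the data were seen. Of 31 genes on the EGFR ligand and growth factor list, 11 were in the table of the WT response and 9 of these fell, led by the EGF family ligand Epgn (-4.72 in WT and -3.15 in KO) and Wnt4 (-3.86 and -3.06), with Areg at -2.01 and -0.63, while Pdgfb rose (2.96 and 2.51). The list median lay at percentile 2.90 in WT and 19.8 in KO, inside the central 95% of random lists. Of 13 listed glycolysis and hypoxia genes 11 fell in WT, including the prolyl hydroxylase Egln3 (-3.02 and -4.86), the phosphofructokinase Pfkl (-1.86 and -2.86) and Pdk1 (-1.66 and -2.21). Of 13 clusters of 12 listed immediate early genes, 8 fell, among them Egr1 (-1.63 and -1.72), Jun (-1.88 and -1.68) and Klf4 (-2.02 and -2.42), while Dusp4 (4.77 and 4.54) and Ctgf (3.53 and 2.95) rose. Of 12 listed DNA replication genes 10 rose in WT, such as Mcm2 (1.59) and Pold1 (1.66), and 0 of 12 rose in KO, where Mcm2 was 0.16 and Pold1 -0.70. Members chosen for a large difference in WT tend to have a smaller one in KO by construction. All 7 listed p53 targets rose in WT and were also higher with IL-4 in KO, 4 of them by at least 2-fold. Their median was 1.38 in WT and 1.10 in KO. The increase was larger in KO only for Gadd45a (2.03 and 4.02) and Mdm2 (1.38 and 1.57). The list medians of the glycolysis (7.48 in WT and 4.17 in KO), DNA replication (95.1 and 62.4) and p53 lists (89.0 and 89.7) lay at percentiles inside the central 95%. Areg and Pold1 were under the 95th percentile of the negative control rows, 9.21, on every array.

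Several genes with a large rise in WT had a smaller increase in KO, which for Flt1 did not reach 2-fold. The difference between the genotypes was not tested. Mmp9 was 5.27 in WT and 2.69 in KO, Calcb 6.22 and 3.60, Tnf 4.61 and 1.91, and Flt1 3.14 and 0.45. Others with a large rise in WT had as large a rise in KO, such as Il24 (6.68 and 7.43), Lif (3.72 and 3.91) and Cxcl2 (2.98 and 3.07, under 9.21 on every array). The starts of Flt1 and Hmgb1 lie 1.49 Mb apart on chromosome 5. Within 10 Mb of Hmgb1, 2 of the 833 placed genes listed as different between KO and WT with IL-4 were found, besides Hmgb1, Flt1 being the larger difference.

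Some genes had their highest value on the WT untreated array, picked because their differences were large: Slc7a3 was 11.18 there and 6.98 to 9.36 on the other 3 arrays, Trib3 was 11.45 against 8.81 to 10.52, and Aldh18a1 was 11.94 against 9.30 to 10.58. That array enters both the IL-4 response in WT and the untreated genotype difference. The cluster with 2 predicted pseudogene symbols that passed the genotype threshold in the additive model was 12.66 and 12.35 in the WT arrays and 6.25 and 7.41 in the KO arrays, a profile close to that of Hmgb1. Melanocyte genes were detected, with Tyrp1 at 12.55 in untreated WT.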
